A study of Homo sapiens with 5 samples.

How the data were processed

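RNA from cultures of H1, a human embryonic stem cell line, was measured on Illumina expression BeadChips, which read each transcript with 1 or more probes of fixed sequence. Per the labels, cells grew in E8, a chemically defined medium, on Matrigel, total RNA was isolated with RNAiso Plus, and biotin-labelled cRNA was made with the TargetAmp-Nano kit. There were 5 arrays, 1 for each of 5 conditions, which were E8 for 2 days, E8 with 16 mM added pyruvate for 2 days, E8 with BMP4 for 2 days, E8 with BMP4 and 16 mM pyruvate for 2 days, and the last mixture for 6 days. Groups were taken from the treatment named in each sample's labels. No group had a replicate, so single comparisons carry no test and no error between cultures, and the number of arrays limits their precision.

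The deposited table of intensity values holds 1 summarized signal per probe and array, not normalized, per the file headers, and the deposited detection p-value of each probe stands beside it. The scanner software and its settings are not given in the sources used here. A second deposited table holds log2 values, whose making is not stated. In each of its columns the value never fell as the same array's intensity rose, the columns had nearly equal medians (5.58 on all 5 arrays), and over the dimmest 10% of probes the median linear value lay 99.2 to 111 units below the intensity. These log2 values were therefore read, from the values alone, as quantile normalized after subtraction of a background. The method behind them stays unknown, and they were used only as an alternative. All 10 columns of per-sample intensities and detection p-values were used.

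The intensities were corrected for background with limma's neqc, which fits the normexp model from the detection p-values, adds an offset of 16, normalizes the 5 arrays by quantiles and takes log2. Quantile normalization gives every array the same distribution, so a change in the total amount of RNA per cell cannot be seen, and a difference is relative to the other genes on the array. The offset shrinks the differences of dim probes. A probe counted as detected on an array at a detection p under 0.01. The arrays detected 16661 to 18982 of 47296 probes, 35.2% to 40.1%. Probes were named from the platform annotation, where 30105 had 1 gene symbol, 8 had several and 17183 had none. Of the named probes, 30066 matched a gene of the RefSeq table of GRCh38.p14 by Entrez identifier, and 0 symbols had to be updated. The files name no genome build, so no coordinates are given. The 30105 probes stood for 20041 genes, 6689 of them with over 1 probe. For those genes the probe with the highest mean normalized value over the 5 arrays was used, and 12418 genes were detected on at least 1 array.

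The comparisons, gene lists, tests and rule for named genes were fixed before the data were examined. They were pyruvate against E8, BMP4 against E8, BMP4 plus pyruvate against BMP4, BMP4 plus pyruvate against pyruvate (all at day 2), day 6 against day 2 of BMP4 plus pyruvate, and day 6 of that mixture against E8 at day 2. A gene counted as higher or lower at an absolute log2 difference of 1 or more, which is 2-fold, if it was detected on the brighter array. This is a rule of size and not a test. Where all probes of a gene were undetected on the dimmer array, only a bound is given, as "at least N-fold". It sets the bright value against the higher of the dim probe's own value and the lowest normalized value of any detected probe on that array. Fixed lists of genes, 35 in number, covered lineage markers, signalling targets, metabolism and stress. They held 722 genes with a probe, and 59 further entries had no named probe and were not analysed here. A list's median over members detected on either array was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. This percentile describes these arrays only. A list could be described where 3 or more members passed the size rule or its median lay outside the middle 95% of random lists. The text describes a selection of these, made after the values were seen, and leaves others out.

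The rule for named genes takes, in each comparison, the 6 genes with the largest positive and the 6 with the largest negative difference among those with a proper symbol and detected on both arrays. It adds the 4 genes in each direction with the largest bound among genes detected on 1 array, up to 4 members of each described list with the largest absolute difference, and 15 lineage markers in every comparison (POU5F1, NANOG, SOX2, TBXT, MIXL1, EOMES, MESP1, HAND1, GATA4, GATA6, ID1, GATA3, CDX2, SOX17 and PAX6). The text leaves some of them out.

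The 4 arrays of day 2 form a cross of BMP4 and pyruvate, and limma's lmFit and eBayes with a trend were fitted to them with both factors as additive terms, on the 11978 genes detected on at least 1 of the 4. The fit has 1 residual degree of freedom, the departure from additivity, which is no replicate error. The estimated prior degrees of freedom were infinite, so that all genes of 1 signal level shared 1 spread, and a gene whose pyruvate response truly depends on BMP4 adds to it. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences of comparisons that share no array were correlated across genes, which are not independent replicates, so no p is given, and overlaps stand beside the number that independent lists would share.

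The factor fit and the size rule were tested on simulated data for BMP4, with the spread of the fit and 200 of 11978 genes changed. The fit recovered 49.3% of genes changed by a log2 of 1, 97.0% of those changed by 2 and 100% of those changed by 3, with 9 false calls. The noise was drawn at the moderated spread of the fit, a choice made after a first version of the simulation had not recovered its known changes. In a pair of these simulated arrays, without the detection filter, the size rule passed 59.7%, 98.5% and 100% of the changed genes and also 305 unchanged ones. That spread holds the departure from additivity, so 305 can overstate the number for real arrays. For BMP4 at day 2, 60 simulated lists of 20 genes gave 3 medians outside the middle 95% of random lists with no shift, and 56 with a shift of 0.5.

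Alternatives were scaling to a common 75th percentile in place of quantiles, no background correction, an offset of 50, the deposited log2 values, a detection p under 0.05, no detection filter, detection on both arrays (all 4 for the factor fit), the mean over a gene's detected probes, size rules of 1.5-fold and 3-fold, eBayes without the trend, and 2 arrays against 2 without the other factor. Counts without the genes peculiar to 1 array were added after seeing the data, as were a set of non-polyadenylated RNAs picked by the pattern of their symbols, a short set of genes linked to the zinc sensor MTF1, the counts of genes on which an array stood apart, and the counts of genes whose second probe also passed the size rule. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.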

Results

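The arrays measured transcript levels in H1 human embryonic stem cells kept in E8 medium or given pyruvate, the end product of glycolysis, BMP4, a growth factor used to start mesoderm differentiation, or both. The series title asks whether added pyruvate raises mesodermal differentiation through metabolism and the AMPK and mTOR pathway. The arrays read transcripts and not the activity of AMPK or mTOR, so the counts for that list below do not test the pathway. Each condition had 1 array, so no difference below has a replicate check, and no p-value is given for a comparison of 2 arrays. Differences are log2 of the normalized signal, and genes undetected on the dimmer array are given by a bound ("at least"). Between 35.2% and 40.1% of the 47296 probes were detected per array. The array of BMP4 plus pyruvate at day 2 stood apart from the other 3 of that day. Of 9728 genes detected on all 4, it lay at least 0.5 above the other 3 in 430 genes and below them in 594, where the other 3 lay within 0.5 of each other. The same counts were 84 and 80 for pyruvate, 43 and 36 for BMP4 and 37 and 41 for E8.

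**Figure D1:**
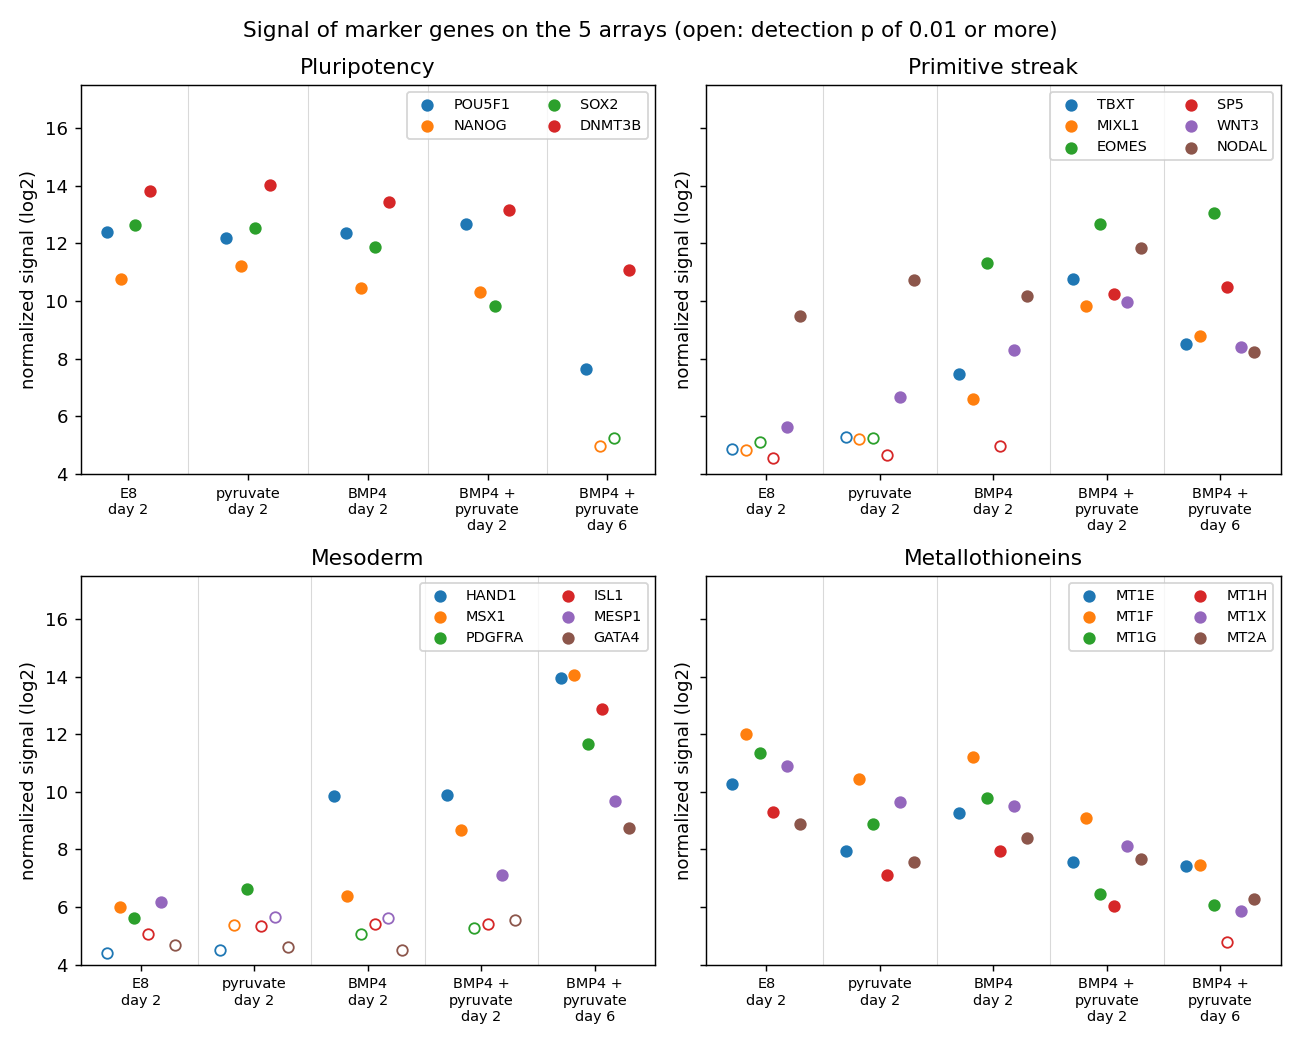
Normalized signal (log2, vertical axis) of marker genes on each of the 5 arrays (horizontal axis), in panels for pluripotency, primitive streak, mesoderm and metallothionein genes, with 1 point per gene and array and open points where detection failed. TBXT, MIXL1 and EOMES were detected only on the 3 arrays with BMP4, NANOG and SOX2 were undetected on the day 6 array, and MT1G was lower on each of the other 4 arrays than in E8.

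Pyruvate alone, against E8 at day 2, was accompanied by higher transcripts of the NODAL pathway, which patterns the early embryo. Of 9 detected NODAL and activin targets, 4 were higher, 0 were lower and 5 were neither. LEFTY2 and LEFTY1, secreted inhibitors of NODAL, were 3.52-fold and 3.01-fold higher, NODAL itself 2.39-fold and GDF3 2.06-fold. The list's median difference was 0.68, at percentile 100 of random lists. Metallothioneins, small proteins that bind zinc and copper, went the other way, with 6 of 6 lower and a median of -1.86 (percentile 0). MT1G was 5.45-fold lower, MT1E 5.02-fold and MT1H 4.54-fold, while a further probe of MT1H differed by -0.98. Among the largest other differences, TIMP4, an inhibitor of matrix metalloproteinases, was 5.23-fold higher, HAS2, which makes hyaluronan, 3.85-fold, and the hyaluronan receptor CD44 was higher by 1.58 in log2.

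Markers of germ layers differed less in this comparison. Of 6 detected primitive streak genes, which mark cells leaving pluripotency for mesoderm and endoderm, FGF8 (2.73-fold), NODAL and WNT3 (2.06-fold) were higher and 3 were neither, with a median of 0.40 (percentile 99.0). That median lay within the range of random lists under 4 alternatives, such as no background correction (0.15). TBXT, MIXL1 and EOMES were undetected on both arrays. Of 28 pluripotency genes, 1 (GDF3) was higher and 27 were neither, with a median of 0.02. POU5F1 differed by -0.22, with a further probe at 0.77, NANOG by 0.44 and SOX2 by -0.11. In the AMPK and mTOR list, 2 of 29 genes were lower (SESN3 and FLCN), 27 were neither, and the median was -0.03 (percentile 30.1). TXNIP, an inhibitor of thioredoxin that also restrains glucose uptake, was the 1 of 20 pyruvate and lactate genes that passed the size rule, 2.38-fold lower, while the list's median was 0.19 (percentile 99.6). Cardiac and smooth muscle genes had a median of -0.28 (percentile 1.78), or 0 with bounds, with TNNI3 and TPM1 lower and ACTA2 higher of 11. Of 43 oxidative phosphorylation genes 1 was lower, with a median of 0.09 (percentile 97.6). No member of the ATF4 target list (26 genes, median 0.19, percentile 99.9), of the list of matrix and epithelial-mesenchymal genes (19 genes, -0.22, percentile 0.20) or of the autophagy and lysosome list (17 genes, -0.13, percentile 2.38) passed. In all, 120 genes were higher and 152 lower of 11475 detected (11 and 12 without background correction). These 272 calls are fewer than the 305 unchanged genes that passed in the simulated pair, so noise could give a count of this size. That pair had no detection filter, and 305 can overstate the number for real arrays. With scaling to the 75th percentile the split was 159 and 94, so 44.1% of calls were higher with quantile normalization and 62.8% with scaling.

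BMP4 alone, against E8 at day 2, went with higher transcripts of its known targets. Of 15 detected BMP target genes, 10 were higher, 0 were lower and 5 were neither, with a median of 2.00 (percentile 100). ID1, an inhibitor of basic helix-loop-helix factors, was 3.87-fold higher, the decoy receptor BAMBI 6.69-fold and MSX2 at least 12.4-fold. Transcription factors of early mesoderm and of extraembryonic lineages appeared with it. EOMES, of the primitive streak, was at least 55.4-fold higher, TFAP2A, of trophoblast and amnion, at least 58.7-fold and HAND1, of extraembryonic and lateral mesoderm, at least 20.5-fold. HPGD, which inactivates prostaglandins, was 31.6-fold higher and ANXA1 10.4-fold.

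By group, 4 primitive streak genes were higher with BMP4 (EOMES, WNT3, TBXT and MIXL1), 1 (CYP26A1) was lower and 4 were neither. TBXT was at least 3.86-fold higher and MIXL1 at least 2.12-fold. The list's median of 0.71 rested on genes undetected in E8. Over the members detected on both arrays, which leave out EOMES, TBXT and MIXL1, it was -0.08. Of 10 mesoderm genes, 5 were higher and 5 were neither (median 0.75), and of 12 trophoblast and amnion genes 5 were higher and 2 lower (median 0.78). Pluripotency genes lay slightly lower, with a median of -0.38 (percentile 0). PRDM14, LCK, UTF1 and KLF4 were lower, the neuropeptide gene GAL was 3.96-fold higher and 23 of 28 were neither, including SOX2 (-0.76), NANOG (-0.32) and POU5F1 (-0.01). Of 13 neuroectoderm genes, SIX6 (8.70-fold), POU3F1, OTX2 and SOX3 were lower and 9 were neither. Of 6 metallothioneins, 4 were lower, with a median of -1.17. The AMPK and mTOR list had 2 of 29 genes lower, DDIT4 and DDIT4L. Of 12 cardiac and smooth muscle genes 4 were higher and 1 lower (median 0.33), and of 19 matrix and epithelial-mesenchymal genes FN1, THBS1 and MMP9 were higher (0.32). EGLN3, ADM and BHLHE40 were the higher of 19 hypoxia genes (0.10), and JUN and IER3 of 12 immediate early genes (0.44). No glycolysis gene of 20 passed, with a median of -0.17 (percentile 0.04). In all, 310 genes were higher and 291 lower of 11559 (99 and 49 without background correction). The split was 364 and 180 with scaling to the 75th percentile, or 66.9% higher instead of 51.6%.

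Adding pyruvate to BMP4, the comparison nearest to the question in the title, went with higher primitive streak genes. Of 14 detected members, 13 were higher, 1 (CYP26A1, which degrades retinoic acid) was lower and 0 were neither. Only 9 members of the list were detected on the BMP4 or the E8 array. Members detected only with BMP4 plus pyruvate, such as CDX2 (at least 1.10-fold), could not count as lower. TBXT, the classical marker of the streak, was 9.93-fold higher, MIXL1 9.34-fold, WNT5B 3.80-fold, NODAL 3.19-fold and EOMES 2.56-fold, and SP5, a target of WNT signalling, was at least 20.6-fold higher. The median was 1.63 (percentile 100), or 1.40 with undetected genes set at their bounds. Of 13 cardiac and smooth muscle genes 9 were higher and 1 lower, with a median of 1.81, or 1.14 with bounds, where pyruvate in E8 had a median of -0.28, or 0 with bounds. They included the actins ACTA1 (2.20 in log2) and ACTC1 (4.59-fold) and CNN1 (3.75-fold). Of 11 mesoderm genes, MSX1 (4.85-fold), TWIST1 (at least 3.79-fold), GATA6 (at least 1.33-fold) and MESP1 (at least 2.34-fold) were higher, FOXC2 (at least 2.11-fold) was lower and 6 were neither.

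BMP target genes did not share this difference. Of 15, only MSX1 and GREM1 were higher, 0 were lower and 13 were neither, with a median of -0.02 (percentile 48.8), and HAND1 differed by 0.02. Of 9 NODAL targets, CER1 (5.38-fold) and NODAL were higher and 7 were neither (median 0.69), among them LEFTY1, at -0.59 here and 1.59 in E8, and of 8 WNT targets SP5, NKD1 and LEF1 were higher (median 0.75). SOX2, a core pluripotency factor, was 4.14-fold lower and USP44 2.62-fold, while POU5F1 (0.30), NANOG (-0.12) and 23 more of the 27 pluripotency genes were neither. That list's median, -0.21 at percentile 2.39, lay within the range of random lists under 5 alternatives, such as scaling (-0.29). Markers of the other lineages differed less evenly. CER1, SOX17 (at least 2.74-fold) and GATA6 were the higher of 8 endoderm genes, KIT was lower, and 1 of 12 trophoblast and amnion genes was higher and 1 lower. The endoderm median of 0.50 rested on genes undetected with BMP4 alone and was -0.49 over members detected on both arrays, which leave out SOX17 and GATA6.

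Metallothioneins were again lower with pyruvate in BMP4, 5 of 6, with MT1G 10.3-fold and MT1F 4.33-fold lower and a median of -1.81 (percentile 0). TXNIP was 3.54-fold lower, and EGR1, an immediate early gene, 4.75-fold. Of 28 ATF4 targets, which respond to amino acid shortage and other stress, CHAC1 (at least 1.71-fold), SLC7A11 (at least 1.10-fold) and SLC3A2 (2.11-fold) were higher and 25 were neither, with a median of 0.47 (percentile 100). Of 20 glycolysis genes, ALDOA (2.27-fold, and 0.56 in log2 by a further probe) and the glucose transporter SLC2A1 (2.11-fold) were higher. In the AMPK and mTOR list, 2 of 27 genes, CASTOR1 and DEPTOR, were lower and 25 were neither (median 0.13, percentile 92.3). On the same array, non-polyadenylated RNAs, a set picked after the data were seen, were lower in 19 of 111 and higher in 0, with a median of -0.29 (percentile 0), and RNU1-3, a U1 spliceosomal RNA, was 5.17-fold lower. In all, 417 genes were higher and 343 lower of 11198 (84 and 61 without background correction). Of 99 genes past the size rule by the first of 2 detected probes, the second probe also passed in 32, against 32 of 48 for BMP4, 5 of 16 for pyruvate in E8, 78 of 199 for BMP4 in pyruvate, 241 of 448 for day 6 against day 2 and 248 of 365 for day 6 against E8. The SD of the difference between 2 probes of a gene was 0.538, against 0.327 for pyruvate in E8 and 0.312 for BMP4. Scaling to the 75th percentile moved the median of all detected genes to -0.14 and the split to 256 and 503, or 33.7% higher instead of 54.9%. Relative to that shift the primitive streak median stayed at percentile 100.

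BMP4 in the presence of pyruvate, against pyruvate alone, shares no array with the comparison of BMP4 against E8. EOMES was at least 108-fold higher, TFAP2A at least 38.9-fold, TBXT at least 29.3-fold, SP5 at least 20.2-fold and HAND1 at least 15.8-fold. Of 14 BMP targets 11 were higher and 0 lower (median 2.02), of 14 primitive streak genes 11 were higher and 1 lower (1.94, or 1.24 with bounds), and of 12 mesoderm genes 8 were higher and 1 lower (1.95). Pluripotency genes were lower in 10 of 28 and higher in 2, with a median of -0.82. They included SOX2 (6.51-fold), KLF4 (4.34-fold) and USP44 (4.14-fold), but not NANOG (-0.88) or POU5F1 (0.50). Of the AMPK and mTOR genes, CAMKK2, a kinase that activates AMPK, was 3.20-fold higher and TSC2, an inhibitor of mTOR, 2.19-fold higher, DDIT4L (3.50-fold) and DEPTOR (3.15-fold) were lower, and 23 of 27 were neither. Of the non-polyadenylated RNAs, 24 were lower, 2 higher and 89 neither (median -0.41). In all, 729 genes were higher and 651 lower of 11282 (254 and 166 without background correction), and the SD between 2 probes of a gene was 0.578. With scaling the median of all detected genes moved to -0.18 and the split to 555 and 939, or 37.1% higher instead of 52.8%.

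The 4 arrays of day 2 hold each treatment in pairs that share no array. Across 11978 genes, which are not independent replicates, the BMP4 difference without pyruvate and the BMP4 difference with it had a Pearson r of 0.491 and a Spearman rho of 0.274. They shared 191 higher genes, where 18.9 would be shared by independent lists, and 133 lower genes, against 15.8. EOMES, TFAP2A, HAND1 and HPGD were high in both. The pyruvate difference without and with BMP4 had r of 0.0985 and rho of 0.0410, with 18 shared higher genes against 4.18 and 29 shared lower genes against 4.35. NODAL, HAS2, CD44 and TIMP4 were higher and MT1G, MT1E and TXNIP lower in both.

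**Figure D2:**
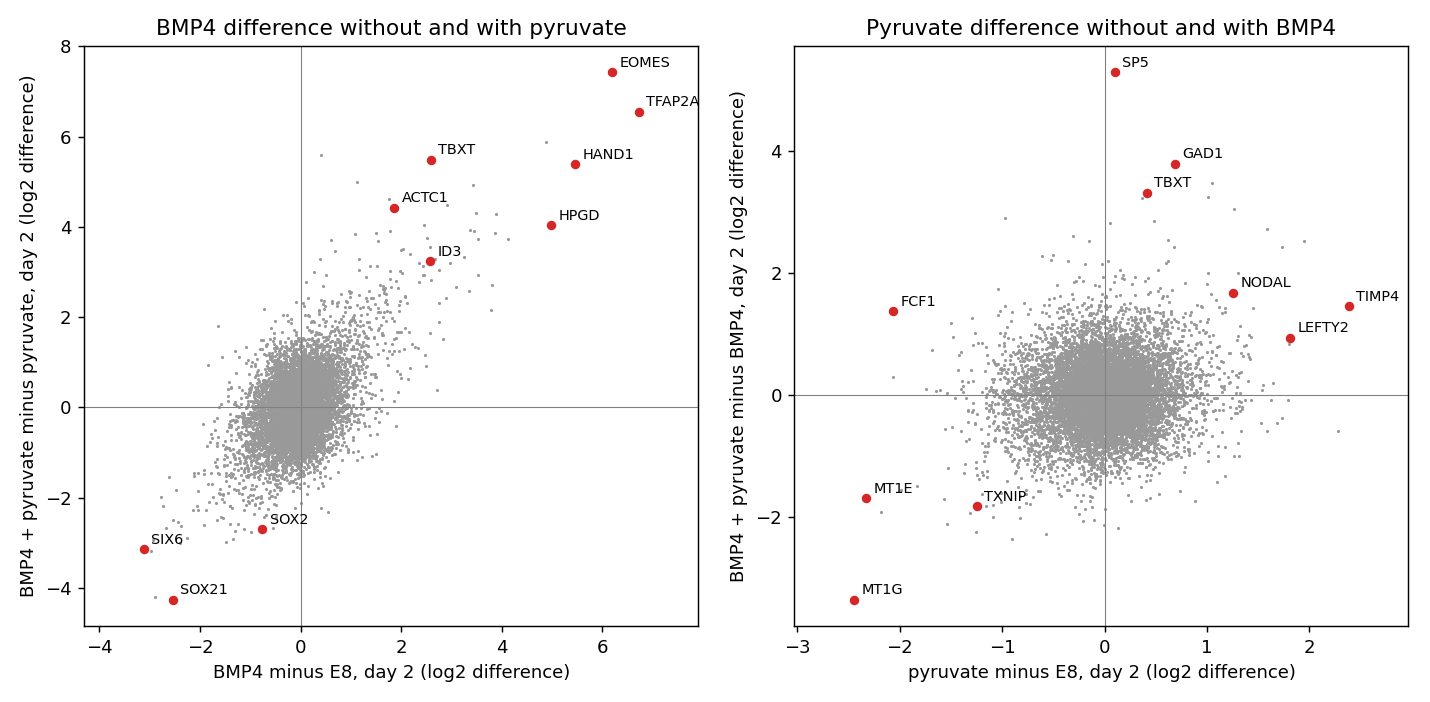
Log2 differences of 11978 genes in pairs of comparisons that share no array, with 1 point per gene and named genes in red. In the left panel BMP4 against E8 is on the horizontal axis and BMP4 plus pyruvate against pyruvate on the vertical axis (r of 0.491), and in the right panel pyruvate against E8 is on the horizontal axis and BMP4 plus pyruvate against BMP4 on the vertical axis (r of 0.0985).

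The additive fit over those 4 arrays takes the departure from additivity as its error, so its p-values measure no spread between cultures. They also depend on the model. For BMP4 the smallest limma adjusted p of any gene was 1.27e-121, but 8.35e-15 without the trend and 7.47e-06 with 2 arrays against 2. By limma, BMP4 went with higher HPGD (log2 estimate 4.51, SE 0.28, adjusted p = 3.30e-56), ID3 (2.91, adjusted p = 9.47e-35) and ID1 (2.11, adjusted p = 6.55e-22), each in both pairs. EOMES, TFAP2A and HAND1 were called as well, but they were undetected without BMP4, so their estimates rest on background signal and are not given. SOX2 fell by 1.73 (limma, adjusted p = 1.37e-13), but this averages -0.76 without pyruvate, short of the size rule, and -2.70 with it. The second value comes from the array that stood apart. SIX6 fell by 3.13 and SOX21 fell by 3.40, while NANOG (-0.60, limma adjusted p = 0.139) and POU5F1 (0.24, adjusted p = 0.702) did not pass. Of 15 BMP targets 12 rose and 0 fell, and adjusted over the list alone 13 rose. Of 28 pluripotency genes 1 rose and 12 fell, and adjusted over the list alone 2 rose and 16 fell. Of 14 primitive streak genes 7 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell. Of 6 metallothioneins 4 fell, and adjusted over the list alone 5 fell. Of 29 AMPK and mTOR genes 1 rose (CAMKK2) and 3 fell (DEPTOR, DDIT4 and DDIT4L), and the counts were the same adjusted over the list alone. In total 402 genes rose and 329 fell with BMP4, and 321 of these 731 differed by 1 or more with the same sign in both pairs.

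For pyruvate, the same fit called MT1G (log2 estimate -2.90, SE 0.27, limma adjusted p = 3.45e-22) and the other metallothioneins, 6 of 6 both over all genes and adjusted over the list alone. NODAL rose by 1.46 (limma, adjusted p = 1.76e-06) and HAS2 by 2.24 (adjusted p = 1.19e-10), and TXNIP fell by 1.54 (adjusted p = 7.41e-06), each with the same sign in both pairs. TBXT, MIXL1 and SP5 were called as well, but they were undetected without BMP4, so these calls rest on the pair with BMP4 and no estimate is given. Of 9 NODAL targets 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. Of 14 primitive streak genes 6 rose and 0 fell, or 8 and 1 adjusted over the list alone. Of 13 mesoderm genes 0 rose and 1, FOXC2, fell, or 2 and 1 adjusted over the list alone. Of 29 AMPK and mTOR genes 0 passed, over all genes or adjusted over the list alone. In total 55 genes rose and 49 fell, of which 39 differed by 1 or more in both pairs. The fit includes the array of BMP4 plus pyruvate that stood apart. Of 127 non-polyadenylated RNAs, the set picked after the data were seen, 0 rose and 5 fell, RNU1-3 among them. Without BMP4 as a term, limma called 0 genes for pyruvate, with 253 at an unadjusted p under 0.05. Without the trend it called 31 and 29, and the smallest adjusted p of any gene was 4.51e-06. That lies above the values given here for MT1G, HAS2 and NODAL, which therefore depend on the trend. Leaving out pyruvate as a term gave 125 higher and 64 lower genes for BMP4.

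The pyruvate difference with BMP4 less the pyruvate difference without it is the departure from additivity, which has no test. Only 6 of the 14 primitive streak genes were detected with or without pyruvate in E8, so for the others the departure mostly restates the difference with BMP4. It had a median of 1.49 (percentile 100) over the 14 primitive streak genes, 1.37 (percentile 100) over 14 cardiac and smooth muscle genes and -0.36 (percentile 0.16) over 28 pluripotency genes. Matrix and epithelial-mesenchymal genes departed by 0.68 (percentile 100) and glycolysis genes by 0.36 (percentile 100). For the matrix list the median without BMP4, -0.22, had the opposite sign of that with it, 0.45, and for the cardiac list the medians were -0.28 and 1.81, or 0 and 1.14 with bounds. The departure was 0.05 (percentile 68.4) over the 6 metallothioneins and -0.10 (percentile 40.2) over 9 NODAL targets. Non-polyadenylated RNAs departed by -0.45 (percentile 0). The primitive streak value was 0.86 without background correction and 0.96 with scaling, each at percentile 100.

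From day 2 to day 6 of BMP4 plus pyruvate, mesoderm genes were higher and pluripotency genes lower. Of 24 mesoderm genes 23 were higher and 1 was neither, with a median of 2.97, or 2.48 with bounds. ISL1, of cardiac and limb progenitors, was at least 147-fold higher, MEIS2 at least 64.7-fold, IRX3 66.0-fold and HAND1 16.9-fold. Of 28 pluripotency genes 18 were lower and 10 were neither (median -1.83, or -1.43 with bounds), with POU5F1 32.8-fold lower, NANOG at least 22.0-fold and SOX2 at least 15.6-fold. Primitive streak genes split, with 8 higher and 6 lower of 17. CYP26A1 (100-fold) and the apelin receptor APLNR (84.0-fold) were higher, while NODAL (12.3-fold), TBXT (4.86-fold), WNT3 (2.95-fold) and MIXL1 (2.06-fold) were lower.

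Genes of other lineages also differed at day 6. Of 13 endoderm genes 9 were higher (median 1.80), among them FOXA2 at least 18.5-fold and SOX17 4.65-fold. Of 12 endothelial and blood genes 9 were higher (1.58), such as LMO2 (24.2-fold) and VWF (at least 16.7-fold), of 15 trophoblast and amnion genes 10 were higher and 1 lower (1.75), and of 12 HOX genes 9 were higher (1.95, or 0.99 with bounds). Matrix and epithelial-mesenchymal genes were higher in 15 of 28 and lower in 1, the epithelial cadherin CDH1. Of 35 cell cycle genes 9 were lower and 1 higher, with MCM5 5.66-fold and CCND1 also lower. Of 27 ATF4 targets 8 were lower and 2 higher, but against E8 at day 2 the same array had 0 lower and 2 higher (median 0.02). Among the 8 were CHAC1, SLC7A11 and SLC3A2, which were higher with pyruvate in BMP4 on the day 2 array that stood apart. TXNIP was 10.6-fold higher and PDK4, a kinase that inhibits pyruvate dehydrogenase, at least 2.25-fold. Of 28 AMPK and mTOR genes, SESN3 (at least 7.25-fold), CASTOR1 (2.44-fold), ULK2 and PRKAG2 were higher, CAMKK2 (5.77-fold), EIF4EBP2 (2.75-fold) and AKT1S1 were lower and 21 were neither. In all 1571 genes were higher and 1511 lower of 11628 (743 and 616 without background correction). No array of BMP4 alone at day 6 was analysed here, so time and treatment cannot be separated, and the SD between 2 probes of a gene, 0.649, was the largest of the 6 comparisons. Scaling moved the median of all detected genes to 0.11.

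At day 6 of BMP4 plus pyruvate, against E8 at day 2, mesoderm genes were again higher and pluripotency genes lower. HAND1 was at least 349-fold higher, EOMES at least 188-fold, APLNR at least 182-fold and ISL1 at least 164-fold, and among genes detected on both arrays MSX1 was 264-fold and the cardiac actin ACTC1 156-fold higher. SOX2 was at least 109-fold lower, NANOG at least 29.8-fold and POU5F1 27.0-fold. Of 24 mesoderm genes 23 were higher (median 4.20, or 3.49 with bounds), of 16 primitive streak genes 13 were higher and 2 lower (3.67, or 2.97), of 28 pluripotency genes 23 were lower (-2.08, or -1.83) and of 6 metallothioneins 6 were lower (-4.53, or -3.99). Of 15 neuroectoderm genes 6 were lower and 3 higher (-0.90), but over members detected on both arrays the median was 0.57. The medians of endoderm genes (2.53) and WNT targets (2.97) likewise turned to -1.20 and -0.01. That filter leaves out genes detected on a single array of the pair, which can itself turn a median. In the AMPK and mTOR list, 2 of 29 genes were higher and 2 lower. In all 1494 genes were higher and 1475 lower of 11992 (759 and 622 without background correction). The pyruvate difference within BMP4 at day 2 shares no array with this comparison. Their r was 0.187 across 12354 genes, and 125 higher genes were shared against 50.4 for independent lists and 119 lower genes against 41.0.

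**Figure D3:**
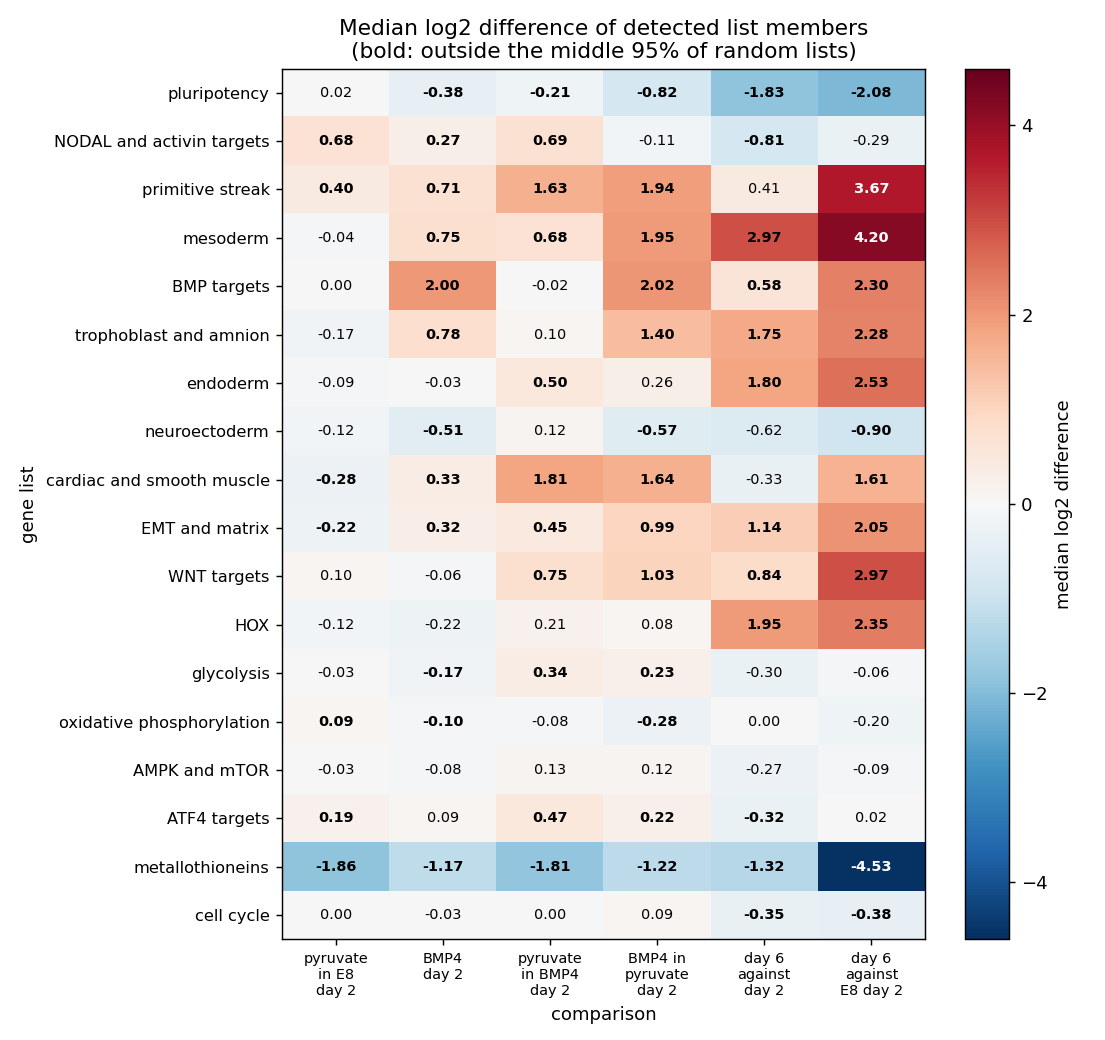
Median log2 difference of the detected members of 18 gene lists (vertical axis) in the 6 comparisons (horizontal axis), coloured from blue (lower) to red (higher), with bold values outside the middle 95% of random lists. Metallothioneins were below 0 in all 6 comparisons, and BMP targets were near 0 in both comparisons of added pyruvate.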

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

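All tests of explanations in this part were chosen after the results were seen. In 22 cases a gene passed the size rule in opposite directions under the same treatment, without and with the other factor, 9 for BMP4 and 13 for pyruvate. None of these differences was tested, since each rests on 4 arrays without replicates. The number of such cases that independent lists would give was not computed. For BMP4 without and with pyruvate, the second difference exceeded the first by 2.55 in AP5B1, 2.1 in FBXO16, 3.44 in FCF1, 2.67 in MIR23B, 2.42 in NUP43 and 2.35 in TMEM191B, and the gap was -2.31 in SPRED3, -2.5 in VWA3B and -2.27 in ZNF596. For pyruvate without and with BMP4, the gap is the same number for AP5B1, FCF1, MIR23B, TMEM191B, SPRED3, VWA3B and ZNF596, because both gaps are the same sum over 4 arrays. It was 2.4 in B4GALT1, 2.78 in DCP1B, 2.03 in MYCL, 2.28 in RBM24, -2.12 in DGKB and -2.1 in DNM3. Among probes without a single gene name, which the comparisons do not use, 347 were higher and 487 lower at day 6 than in E8, of 4357 detected on either array.

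Metallothionein genes were lower with added pyruvate, both without and with BMP4, and they were lower with BMP4 as well (medians of -1.17 without pyruvate and -1.22 with it), so the pattern is not peculiar to pyruvate. Normalization and background correction are argued against, because the list median nearest to 0 over 4 other settings of the values and both comparisons was still -1.15. Reading of a common transcript by all the probes is argued against as the whole source. The SD over the 6 members was 2.31 times the spread expected of probes of the same gene with pyruvate in BMP4 and 2.33 times in E8. That spread is the SD between 2 probes of a gene divided by the square root of 2, and the ratios lie just above the cut of 2. Partial cross-hybridization within the family stays open. Lower activity of the zinc sensor MTF1 may contribute and stays open, since its further target SLC30A1 differed by -0.31 in BMP4 and -0.36 in E8, where the SD between 2 probes was 0.538 and 0.327. An effect of pyruvate on free metal in the medium was not tested.

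Many genes stood apart on the array of BMP4 plus pyruvate at day 2. Normalization is argued against, since the number of such genes was at least 7.01 times that of the next array under 4 other settings. Noise from the RNA or labelling of this array may account for part of it, since the SD between 2 probes of a gene was 0.538 or more in each comparison with this array and 0.469 or less in each comparison without it. Over 113 genes taken as housekeeping, the SD of the deviation from the mean of the other 3 arrays was 0.38 on this array. On the others of day 2 it was 0.19 to 0.27. The combination of BMP4 and pyruvate stays open as well, because the second probe departed the same way in 77.1% of the 253 genes that had a second probe, a share that does not set this array apart from the others of day 2 (65.7% for pyruvate, 80.0% for BMP4 and 100% for E8, over fewer genes). Noise and the combination lie in the same array and cannot be told apart for these genes without a replicate.

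Primitive streak genes were higher when pyruvate was added to BMP4. The list's median of 1.63 exceeded 0.34, the upper limit of the middle 95% of random lists from the same arrays. This repeats the percentile by which the list stood out, so it is no further test. Such lists cover noise that strikes genes independently, which alone would not give this median. They do not cover noise shared by the list's genes or a difference in culture between the 2 arrays, so noise of that array stays open. A stronger BMP4 signal was not seen in the 15 BMP targets as a set. Their median was -0.0184 (percentile 48.8), with quartiles of -0.29 and 0.48, and the additive fit called 0 of them for pyruvate. The test could argue against this signal only if the upper quartile lay below 0. Unchanged targets would not give that, so the test could not decide, and a stronger BMP4 signal stays open. A stronger NODAL signal may contribute, as the 8 NODAL targets outside the primitive streak list had a median of 0.60 (percentile 99.8) in BMP4 and 0.67 (percentile 100) in E8, but in BMP4 only CER1 of these passed the size rule and LEFTY1 lay at -0.59. A faster course of differentiation, or a difference between the 2 cultures unrelated to pyruvate, was not tested.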

How the results depend on the processing

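No analysis paired by replicate was possible because each group had 1 array. Leaving out an array leaves no residual degree of freedom in the factor fit and no pair in a comparison, so it was not run. Of the alternatives for counts, 98 stayed within 1.5 times of the first value and 68 moved further, and the cause was not tested. The detection p under 0.05 and the lack of a detection filter gave the same counts as each other in every comparison and kept them within 1.5 times, as did the mean over probes. Counts without the genes on which the BMP4 plus pyruvate day 2 array lay above (49) or below (31) the other 4 arrays moved by less as well. This alternative was chosen after the data were seen, and so few genes could not move the counts by 1.5 times. It did not leave out all of the 430 and 594 genes on which that array stood apart at day 2, so it says little about them. The signal over background limits the difference that a dim probe can show.

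For pyruvate in E8, higher and lower genes numbered 11 and 12 without background correction, 28 and 43 with an offset of 50, 53 and 80 with the deposited values, 55 and 53 with detection on both arrays, 592 and 817 at 1.5-fold and 12 and 11 at 3-fold, and scaling left 94 lower. For BMP4 the same settings gave 99 and 49, 169 and 114, 190 and 128 with detection on both arrays, 741 and 993 at 1.5-fold and 113 and 57 at 3-fold, with 181 lower in the deposited values and 180 lower with scaling. For pyruvate in BMP4 they gave 84 and 61, 186 and 162, 255 and 206 with the deposited values, 1400 and 1352 at 1.5-fold and 72 and 46 at 3-fold, with 229 higher when detected on both arrays and 256 higher with scaling. For BMP4 in pyruvate they gave 254 and 166, 445 and 359, 1751 and 1900 at 1.5-fold and 238 and 138 at 3-fold, with 441 higher when detected on both arrays. For day 6 against day 2 the counts were 743 and 616 without background correction, 2820 and 2830 at 1.5-fold and 734 and 584 at 3-fold, with 978 lower when detected on both arrays. For day 6 against E8 they were 759 and 622, 952 and 843 with detection on both arrays, 2617 and 2842 at 1.5-fold and 773 and 687 at 3-fold.

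In the factor fits, BMP4 had 125 higher and 64 lower genes with 2 arrays against 2, and pyruvate had 0 and 0. Whether these are the same genes was not examined. Pyruvate had 31 higher and 29 lower genes without the trend and 34 higher among genes detected on all 4 arrays.

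Of the medians of the pluripotency, primitive streak, mesoderm and BMP target lists, 146 kept their call, 10 lost it, 2 gained one and 1 turned. The primitive streak median for pyruvate in E8 was 0.15 without background correction, 0.27 with an offset of 50, 0.29 with the deposited values and 0.0346 without a detection filter. For BMP4 it was 0.053 without a detection filter and -0.081 over members detected on both arrays. From day 2 to day 6 it was 0.66 with scaling and 0.41 without background correction, both now outside the range of random lists. The pluripotency median for pyruvate in BMP4 was -0.29 with scaling, -0.11 without background correction, -0.17 with an offset of 50, -0.17 with the deposited values and -0.15 with the mean over probes. For other lists, members detected on both arrays turned the endoderm median for pyruvate in BMP4 to -0.49. Against E8 at day 6 they turned the endoderm median to -1.20, the neuroectoderm median to 0.57 and the median of WNT targets to -0.0075. Genes detected on a single array of the pair drop out under this alternative. Scaling turned the glycolysis median for BMP4 in pyruvate to -0.14, but it also moved the median of all detected genes to -0.18. Relative to that shift the list did not turn. The other lists kept 751 calls, lost 51 and gained 15. Of values for named genes, 4411 kept their call, 476 lost it and 17 gained one. The correlations across genes for BMP4 and for pyruvate at day 2 moved by less than 0.1. Departures from additivity were examined for the primitive streak and metallothionein lists, which kept their side of the random range, but that of the primitive streak was 0.86 without background correction and 0.96 with scaling, against 1.49.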

Other observations

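The sets in this paragraph on non-polyadenylated RNA and on genes linked to MTF1 were chosen after the data were seen, and the other lists before. Of 17 TCA cycle genes 0 passed the size rule with pyruvate in either comparison, and of 43 oxidative phosphorylation genes only NDUFA5 was lower without BMP4 and only NDUFA9 higher with it. Among genes of the response to oxidants, NQO1 and HMOX1 were higher with pyruvate in E8, 2 of 15, and SLC7A11 was higher in BMP4, 1 of 16. By limma, NQO1 rose by 1.19 with pyruvate (adjusted p = 3.92e-04, higher in both pairs) and the malic enzyme ME1 by 1.07 (adjusted p = 0.0233, higher in both pairs). Of 18 p53 targets, 5 were higher with BMP4 in pyruvate (ZMAT3, GADD45A, GDF15, BAX and CDKN1A) and 13 were neither, on the array that stood apart. Of 11 genes of one-carbon metabolism and DNA methylation, 5 were lower at day 6 than in E8, with DNMT3B 6.60-fold lower and TET1 2.36-fold lower. Non-polyadenylated RNAs differed little with pyruvate alone (median 0.05) or BMP4 alone (median 0.01) and were lower in 31 of 117 at day 6 against E8 (median -0.60). Of 3 genes linked to MTF1, 0 passed with pyruvate in E8 and 1, the zinc importer SLC39A10, was lower with pyruvate in BMP4.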
